A study of Homo sapiens with 24 samples.

How the data were processed

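The deposited data were 4 tables, one per FGF23 comparison, each with 6 libraries. Per the file headers each table held raw counts per gene, counts divided by a size factor per library (the signal columns of the authors) with their group means, FPKM values, the authors' log2 fold change of FGF23 over control, their p-value and adjusted p-value, and gene annotation with gene length in bases. The authors' test, aligner, counting program and stranding are not stated. Gene coordinates matched human GRCh38, with 34299 of 34305 gene IDs at the same start and end in GENCODE release 29, whereas the labels name the genome build mm10. Libraries were made with an NEBNext Ultra RNA kit from RNA isolated on Nucleospin columns and sequenced commercially at Novogene.

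From the deposited counts all 24 libraries were joined. The 4 tables listed 34305 genes together and 25355 in common, a gene absent from a table was taken as 0, and the most counts in any library of a gene absent elsewhere was 30. Genes passing filterByExpr by group, 17790, were tested in edgeR 4.0.16 with TMM scaling, a robust quasi-likelihood fit to 8 group means with 16 residual degrees of freedom, and Benjamini-Hochberg adjustment within each of 10 contrasts. CPM values are counts scaled to a common total with the TMM factors, except those of KL, which are counts over the library total without these factors. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over lists within a contrast, where 5 or more members were tested. Chosen after the values were seen were the receptor complex list without KL and the lists in WT with a trend of the signed statistic with gene length removed. DESeq2 1.42.0 and limma voom served as alternatives. R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.

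The tests, the gene lists, the alternatives and the rule for naming genes were chosen before the data were examined, except where stated. By that rule each contrast names the 10 highest and 10 lowest fold changes among genes with a symbol, an adjusted p under 0.05, a mean CPM of at least 1 and, between 2 groups, no overlap between their libraries. In a comparison of 3 with 3 libraries such separation arises by chance in 10% of genes. It adds up to 4 members with the smallest p from each list that passed, and 11 fixed genes, KL, FGFR1 to FGFR4, EGR1, FOS, DUSP6, SPRY4, ETV4 and ETV5. Genes named elsewhere for a list or for a shared location were chosen after the values were seen. A few genes that the rule selects are not reported here.

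The 26 lists cover the FGF23 receptor complex, ERK immediate-early, FGF-ERK feedback, phosphate and vitamin D, calcineurin-NFAT, WNT target, FOXO and insulin-IGF, SRF-MRTF cytoskeletal, NF-kB inflammatory, TGF-beta and matrix, interferon response, cholesterol synthesis, ATF4 and unfolded protein response, hypoxia and glycolysis, heat shock, NRF2 oxidative stress, S phase, G2 and mitosis, replication-dependent histone, ribosomal protein and mitochondrially encoded genes, and markers of proximal tubule, distal nephron and collecting duct, neuronal and adrenal, fibroblast and endothelial, and blood cells.

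Alternatives were RLE size factors, library size only, no filter, a stricter filter (CPM of at least 1 in 3 libraries), DESeq2, only the libraries of the contrast, each library left out in turn and the replicate number as a block. Added after the values were seen were limma voom with a separate spread for each group, the fit without library 1 of the Kl cells treated for 1 h, removal of the GC trend from each library (lowess, span 0.3, 17782 genes with GC content), and that removal with only the libraries of the contrast. The labels do not establish that equal replicate numbers belong together, so pairing was not used in the main fit. Deviations of same-numbered libraries from their group means correlated by at most 0.12 between treated and control. At 1 h they were highest for the same number in every case, with 0.05 to 0.1 in WT and 0.06 to 0.12 in Kl. Other numbers reached at most 0.02 and 0.03, so pairing at 1 h is not excluded. At 24 h no such order was seen, with 1 of 3 in each line.

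Each path was tried on simulated counts of 17790 genes in which known genes changed. Of these, 17457 passed the filter in fits to all libraries, and 16365 to 17064 in fits to the libraries of a contrast. Percentages are of all changed genes, those filtered out included. For FGF23 in Kl at 24 h edgeR found 26, 48, 78 and 92% of the genes changed by 1.25, 1.5, 2 and 4 times, with 1 false call among 123. For FGF23 in Kl at 1 h, simulated with the larger spread of that group, it found 30, 66, 72 and 92%, with 424 false calls among 554. Restricted to its own libraries it found 0, 26, 58 and 92% with 1 false call among 89, and voom found 8, 42, 62 and 86% with 25 among 124. For the difference between lines edgeR found 2, 40, 56 and 90% at 1 h (28 false among 122) and 8, 28, 64 and 84% at 24 h (2 among 94). For 24 h against 1 h in Kl it found 9, 41, 65 and 89% (59 false among 263). Genes were drawn independently and a set number was changed, so the shares of false calls do not carry over to the real counts. An unchanged WT comparison gave 0 calls in edgeR with all or only its own libraries, in DESeq2 and in voom, and 7 false calls with the replicate block. A list simulated as raised was found by camera and an unchanged one was not (0.756 as its p).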

Results

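RNA was sequenced from the human embryonic kidney line HEK293, called WT, and from HEK293 cells stably transfected with Klotho, called Kl. Klotho (KL) is the membrane co-receptor that lets FGF receptors bind FGF23, a hormone from bone that lowers phosphate reabsorption and vitamin D activation in the kidney. Cells of both lines received recombinant human FGF23 at 0.5 nM for 1 h or at 10 nM for 24 h, and control cells of both lines were collected for each time. The question the design addresses is which transcripts respond to FGF23 only where Klotho is present and which respond without it. There were 8 groups of 3 libraries, 24 libraries in all. Dose and time changed together, so the 1 h and 24 h effects differ in both. The labels do not say that replicates are separate cultures, and the p-values therefore measure the spread between these samples. Total counts per library ran from 15849564 to 30446989, here given as 15.8 M and 30.4 M. At 1 h they were 17.2 to 30.4 M in WT controls and 17.1 to 20.4 M with FGF23, and 15.8 to 17.9 M in Kl controls and 16.6 to 29.4 M with FGF23. At 24 h they were 17.6 to 26.8 M and 16.9 to 17.9 M in WT, and 16.2 to 17.9 M and 18.5 to 29.1 M in Kl. Mitochondrially encoded genes took 5.42 to 7.13% of the counts as group means, with the highest share, 8.27%, in library 3 of the Kl cells treated for 1 h.

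In the principal components of the 24 libraries, the first component (24.7% of the variance) separated every Kl library from every WT library. The second (12.1%) separated the 12 libraries of 24 h from the 12 of 1 h. Below, a gene is called changed where its adjusted p was under 0.05 among the 17790 genes tested, and fold changes are log2 values with their SE from a fit to 3 libraries per group. Between a pair of groups, genes named for the size of their change had no overlap between the 3 libraries of one and the 3 of the other.

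KL itself (ENSG00000133116, GRCh38 chromosome 13, 33016433 to 33066145) marked the transfected line. Its counts were 0 to 14 per library in WT and lay between 991.7 and 2057 CPM (counts scaled to a common library total) in every Kl library. Transcripts of FGF23 were at 0 to 7 counts per library, and those of KLB, the co-receptor of the related hormones FGF19 and FGF21, at 2 to 15.

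In WT cells, FGF23 at 0.5 nM for 1 h gave no call among the genes that report FGF receptor signaling. EGR1 (ENSG00000120738, chromosome 5, 138465490 to 138469315), an early transcription factor gene switched on by the ERK kinases, stood at 0.21 ± 0.197 (SE), and FOS, its partner in that early wave, at -0.23 ± 0.341. DUSP6, a phosphatase gene that shuts ERK off, stood at 0.07, and SPRY4, an inhibitor of receptor signaling to ERK, at 0.47 ± 0.215. ETV4 and ETV5, ETS factors that mark FGF activity in development, stood at -0.62 and 0.02. The receptor gene FGFR1 stood at -0.02, FGFR2 at -0.02, FGFR3 at 0.03 and FGFR4 at 0.06 (adjusted p = 1 for all of these). Among the 34 ERK immediate-early genes 0 were called, also with p adjusted over the list alone, and their median was 0.02 (camera adjusted p = 0.749). Mitochondrially encoded genes as a list lay lower (median -0.1, adjusted p = 0.0067, and 0.774 with an estimated correlation), led by MT-CYB (-0.13) of the respiratory chain. Ribosomal protein genes lay higher (median 0.06, adjusted p = 0.00171, and 0.774 with an estimated correlation), led by RPL7A (0.09). Single members passed in neither list. With a trend with gene length removed, the mitochondrially encoded and ribosomal protein lists still passed (adjusted p = 0.00182 and 0.0029). In edgeR 0 genes were called, with 404 at an unadjusted p under 0.05 against 890 expected by chance. DESeq2 and limma voom called 0 as well, and the deposited adjusted p of the authors gave 0.

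With 10 nM FGF23 for 24 h, WT cells again gave no call among the receptor-signaling genes. EGR1 stood at -0.01 ± 0.182 (SE), DUSP6 at 0.03, SPRY4 at 0.27, ETV4 at -0.19, ETV5 at -0.09 and FOS at 0.51, and FGFR1 to FGFR4 at -0.07, -0.07, -0.03 and 0.00 (adjusted p = 1 for each). The calcineurin-NFAT genes, which carry calcium signals to transcription, lay lower as a list (adjusted p = 0.0131, and 0.417 with an estimated correlation). WT effects at 24 h were lower in longer genes (rho -0.35), and with that trend removed the list did not pass (adjusted p = 0.0919). Its foremost members were ITPR2, a calcium channel of the endoplasmic reticulum (-0.20), the phosphatase subunit PPP3CC (-0.27), NFATC1 (-0.21) and NFAT5, the osmotic stress factor (-0.20), and none of these passed on its own. Ribosomal protein genes, led by RPLP1 (0.15), lay higher (adjusted p = 9.19e-05, and 0.702 with an estimated correlation). With the length trend removed that list still passed (adjusted p = 0.000678). Immediate-early and feedback genes had list p-values of 0.843 and 0.92. In edgeR 0 genes were called and 541 had an unadjusted p under 0.05, against 890 expected by chance. That fit, like DESeq2, estimates the spread of a gene over all 24 libraries, the wide Kl libraries treated for 1 h included. Their median SD of log2 CPM was 0.205, against 0.068 and 0.077 in these WT groups, so 0 calls do not show that nothing changed. The same spread enters the WT fit at 1 h. DESeq2 called 0 and limma voom 2, while edgeR restricted to the 6 libraries compared called 111, of which 17 lay higher and 94 lower. In that restricted fit ITPR2 and NFAT5 fell, with adjusted p = 0.031 and 0.0453, against ranges over all alternatives of 0.0156 to 1 and 0.0205 to 1. The deposited adjusted p of the authors called 211 (41 higher, 170 lower), all in the same direction as in the fit here. Both rest on the same counts, so the shared direction is no independent check.

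In Kl cells, 1 h of FGF23 raised the early transcription factor genes that ERK controls. EGR1 went from 4.96 ± 0.863 CPM (SD, n = 3) to 818 ± 234 (SD, n = 3), while it stood at 7.02 and 8.31 CPM in WT cells. Its log2 fold change was 7.37 ± 0.187 (SE, adjusted p = 2.14e-17). The related zinc finger genes EGR3 (ENSG00000179388, chromosome 8), EGR4 (chromosome 2) and EGR2 rose by 7.83 ± 0.42, 7.71 ± 0.515 and 6.48 ± 0.274 (adjusted p = 8.22e-10, 5.05e-12 and 1.18e-15). FOS (ENSG00000170345, chromosome 14, 75278774 to 75282230) and FOSB, which pair with JUN proteins in AP-1, rose by 5.46 and 5.45, and ARC, an activity-regulated gene best known at synapses, by 5.01. MAFF, a small partner of leucine zipper factors, rose by 3.79, PTGS2, the inducible prostaglandin synthase, by 3.18 and GPR3, a receptor that raises cyclic AMP, by 2.97. ZFP36, which destabilizes early mRNAs, rose by 2.70, and BTG2, a brake on proliferation, by 1.20.

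**Figure D1:**
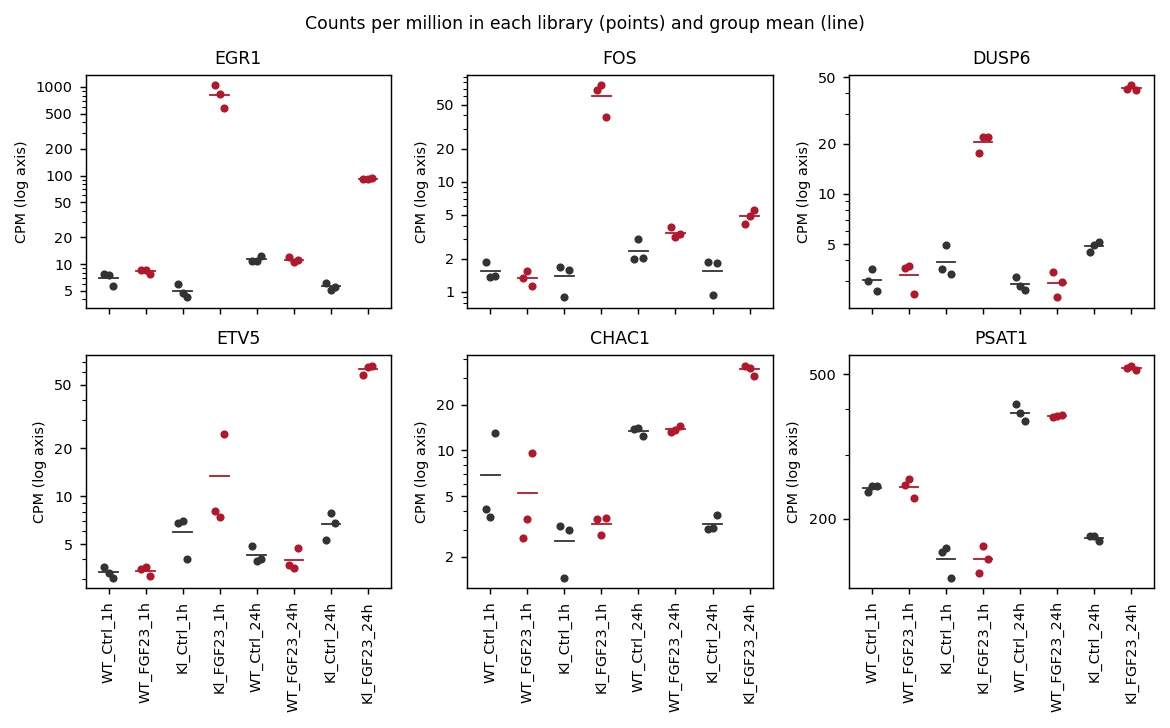
CPM on a log axis of EGR1, FOS, DUSP6, ETV5, CHAC1 and PSAT1 in each of the 24 libraries, with points for libraries and bars for the group means. EGR1 averages 818 CPM in the Kl libraries treated for 1 h and 4.96 in their controls.

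Genes that damp FGF signaling rose in the same hour. SPRY4 rose by 2.97 ± 0.161 (SE, adjusted p = 3.33e-14), DUSP6 (ENSG00000139318, chromosome 12, 89347232 to 89353271) by 2.39 ± 0.144, SPRY2 by 1.37 and the phosphatase gene DUSP1 by 1.26. CTGF and CYR61, matricellular proteins under serum response factor and YAP control, rose by 2.23 and 1.47, and ZYX, a focal adhesion protein, by 0.81. KL rose by 0.68 ± 0.094 (adjusted p = 2.08e-05), from 1156 to 1229 CPM in the controls to 1764 to 2057. With 0 to 14 counts in WT, nearly all of these reads belong to the transfected construct, whose promoter is not stated, so this and the 24 h rise of KL are not shown for the native gene. ID1, a BMP target that blocks differentiation factors, rose by 0.85, CEBPB, a stress and fat cell regulator, by 0.92, and INSIG1, which holds back sterol synthesis, by 0.72. FGFRL1, FGFR3 and FGFR1 passed at 0.60, 0.40 and 0.29, while FGFR2 (0.08, adjusted p = 0.599), FGFR4 (0.28, adjusted p = 0.0776), ETV4 (0.67, adjusted p = 0.143) and ETV5 (1.19, adjusted p = 0.0629) did not. TXNIP, a thioredoxin inhibitor that follows glucose, fell by 0.96 (adjusted p = 3.8e-05). The other larger decreases were those of TBC1D3G (-2.32), one of several near-identical copies and thus uncertain, the transcripts AC098934.2 and LINC02600, ZNF192P1, RIN2, TARID, ZNF610, the HOXA-locus transcript HOTTIP (-0.90) and AL353763.1. With only the 6 libraries compared TXNIP, TBC1D3G and ZNF192P1 alone of these decreases kept their call, and with a separate spread for each group TXNIP alone, and TXNIP lost it in those 6 with the GC trend removed (adjusted p = 0.136, range over all alternatives 2.08e-17 to 0.136).

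As lists, the immediate-early genes stood first, with 32 of 34 called higher, 34 with p adjusted over the list alone, and a median of 1.46 (camera adjusted p = 1.9e-262). Of the 29 FGF-ERK feedback genes 12 rose (19 adjusted over the list alone, adjusted p = 1.57e-33), and of the 21 SRF-MRTF cytoskeletal genes 9 (13 adjusted over the list alone, adjusted p = 1.29e-18). Both held with an estimated correlation, as did the receptor complex (4 of 13 rose, KL included, 5 adjusted over the list alone, adjusted p = 0.000969, and without KL 0.041, or 0.12 estimated) and the ATF4 and unfolded protein response genes, where 5 of 27 rose and VLDLR fell (9 and 1 adjusted over the list alone, adjusted p = 0.000678). Cholesterol synthesis genes passed with 4 of 25 called (10 adjusted over the list alone, adjusted p = 0.000104, and 0.167 with an estimated correlation). Hypoxia and glycolysis genes passed with 4, led by NDRG1 (7 adjusted over the list alone, adjusted p = 0.000678, and 0.245 estimated), and TGF-beta and matrix genes with 4 (5 higher and 1 lower adjusted over the list alone, adjusted p = 0.00296, and 0.245 estimated). NF-kB, WNT and heat shock genes passed with 1, 1 and 2 called (2, 1 and 3 higher and 1 heat shock gene lower adjusted over the list alone), and adjusted p = 0.0134, 0.0189 and 0.0318 (0.133, 0.128 and 0.418 with an estimated correlation).

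In all, 859 genes were called, 693 higher and 166 lower, against 3434 at an unadjusted p under 0.05. The treated libraries lay further apart than those of any other group (median SD of log2 CPM 0.205, against 0.068 to 0.103), which the fit to all 24 libraries understates. In simulated tables with that spread, 424 of its 554 calls were false. Those tables drew each gene on its own and changed a set number of genes, so this share does not carry over to the 859. With only the 6 libraries compared 90 genes were called, 87 higher and 3 lower, and with a separate spread for each group (voom) 229, 224 higher and 5 lower, so few of the 166 lower calls held. In the restricted fit 25 immediate-early and 9 feedback genes kept their call, as did CTGF, CYR61, ID1, CEBPB, TXNIP and KL, while INSIG1, FGFR1, FGFR3, FGFRL1, FOSB and ARC did not. FGFR1 then had adjusted p = 0.573 (range over all alternatives 3.71e-05 to 0.573), FOSB 0.0591 (6.76e-215 to 0.152) and ARC 0.105 (6.07e-232 to 0.238). The direction split depended on scaling, with 80.7% of calls higher by default and 56.5% with library size alone. Of the 183 genes called by the authors' deposited adjusted p, 181 were among the 859, in the same direction, from the same counts.

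After 24 h at 10 nM in Kl cells, ETV4 (ENSG00000175832, chromosome 17, 43527844 to 43579620) rose by 4.45 ± 0.229 (SE, adjusted p = 2.62e-13) and ETV5 by 3.25 ± 0.334 (adjusted p = 3.15e-06). EGR1 rose by 4.04 ± 0.179, from 5.59 to 92.3 CPM, and FOS by 1.65 ± 0.287. The inhibitors SPRY4 (ENSG00000187678, chromosome 5, 142310427 to 142326455), DUSP6 and SPRY2 rose by 3.99 ± 0.148 (adjusted p = 5.29e-18), 3.15 ± 0.137 and 1.29. CHAC1 (ENSG00000128965, chromosome 15), which degrades glutathione under the stress factor ATF4, rose by 3.37 ± 0.435 (adjusted p = 6.06e-05), from 3.30 to 34.1 CPM, where WT cells had 13.4 and 13.8. PAPPA2, a protease that frees IGF from its binding proteins, rose by 2.998, the kinase gene ALPK2 by 2.72, ELSPBP1, known from the epididymis, by 2.58 and ASNSP1, a pseudogene of asparagine synthetase whose reads may be shared with ASNS, by 2.91.

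Among the ATF4 and unfolded protein response genes, PSAT1 (ENSG00000135069, chromosome 9, 78297143 to 78330093), an enzyme of serine synthesis, rose by 1.56 ± 0.066 (SE, adjusted p = 1.44e-16), and TRIB3, a pseudokinase that feeds back on ATF4, by 1.38 ± 0.066. The amino acid transporter genes SLC7A5 and SLC7A11, the latter importing cystine for glutathione, rose by 1.62 and 2.24. Among early genes, KLF10 rose by 0.89, MAFF by 1.99 and IER3, a survival gene, by 1.82. CTGF rose by 1.81 and CALD1, an actin-binding protein, by 0.51. PTGS2 rose by 2.40, RELB, a subunit of NF-kB, by 0.87, and TGFB1, the growth factor of fibrosis, by 1.07 with its matrix target FN1 at 0.44. KL rose by 0.89 ± 0.094 (adjusted p = 1.41e-07) and FGFR1 (ENSG00000077782, chromosome 8, 38400215 to 38468834) by 0.52 ± 0.074 (adjusted p = 1.26e-05), while FGFR2, FGFR3 and FGFR4 stood at -0.06, -0.09 and -0.06 (adjusted p = 0.686, 0.575 and 0.769).

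Of the genes lower at 24 h, ACAT2, MVD and LSS, enzymes on the way to cholesterol, fell by 0.45, 0.57 and 0.45, and TM7SF2, a sterol reductase, by 0.59. Over the Kl controls of 1 h the cholesterol genes stood at a median of -0.01 at 24 h, with 6 higher and 4 lower. The chaperone genes HSPA8 and HSPA1A fell by 0.41 and 1.05, the latter with a near-identical neighbor in HSPA1B (-0.87). ALPL, the phosphatase that mineralizes bone, fell by 1.09, PTGES, which makes prostaglandin E2, by 1.09, COL21A1, a fibril-associated collagen, by 1.15, TMEM132B, a neuronal membrane protein, by 1.26 and HMGCLL1, which makes ketone bodies, by 1.38. SYT6 and MYRIP of vesicle traffic fell by 1.07 and 1.06. The largest decreases, SERF1A (-1.81) and SMN1 (-1.54), belong to a duplicated region with near-identical copies and are uncertain, and AC004706.3 (-1.40) has no known function.

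**Figure D2:**
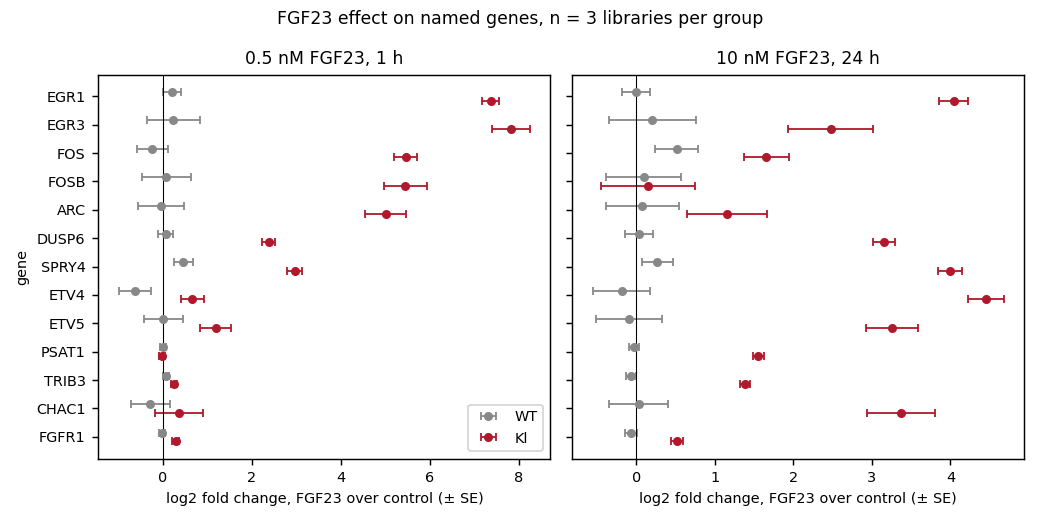
Log2 fold change of FGF23 over control with SE bars for 13 genes in WT and Kl cells at 1 h and 24 h, 3 libraries per group. EGR1 stands at 7.37 in Kl at 1 h and at 0.21 in WT, and ETV4 at 4.45 in Kl at 24 h and at -0.19 in WT.

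By list at 24 h, the ATF4 and unfolded protein response genes stood first, with 17 of 27 higher (18 higher and 1 lower adjusted over the list alone, median 0.7, camera adjusted p = 4.87e-64). The feedback genes followed with 16 of 29 higher and FLRT3 lower (17 and 1 adjusted over the list alone, adjusted p = 6.15e-42). Of the immediate-early genes 21 of 34 were higher and 1 lower (24 and 2 adjusted over the list alone, adjusted p = 1.08e-26). These 3 lists held with an estimated correlation, as did the receptor complex (2 called, KL and FGFR1, 2 adjusted over the list alone, adjusted p = 0.0116, but 0.315 without KL) and the NRF2 oxidative stress genes (3 higher, led by SLC7A11, 3 adjusted over the list alone, adjusted p = 0.00839). Cholesterol synthesis genes lay lower with 9 of 25 called (10 lower and 1 higher adjusted over the list alone, adjusted p = 5.31e-05, and 0.172 with an estimated correlation). TGF-beta and matrix genes had 9 higher and ID2 lower (10 and 1 adjusted over the list alone, adjusted p = 0.000912, and 0.198 estimated), NF-kB genes 3 higher (6 adjusted over the list alone, adjusted p = 0.00308, and 0.0845 estimated) and SRF-MRTF genes 4 higher (5 higher and 1 lower adjusted over the list alone, adjusted p = 0.00505, and 0.172 estimated). G2 and mitosis genes, KIF2C, NEK2, MKI67 and CCNA2, lay higher (5 adjusted over the list alone, adjusted p = 0.00373, and 0.328 estimated). Heat shock genes had 3 lower (3 adjusted over the list alone, adjusted p = 0.00373, and 0.31 estimated) and ribosomal protein genes 4 lower, led by RPS2 (4 adjusted over the list alone, adjusted p = 0.000469, and 0.363 estimated).

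At 24 h in Kl 1524 genes were called, 873 higher and 651 lower, against 3864 at an unadjusted p under 0.05. Here the spread from the 1 h libraries lowers the count, and the fit to the 6 libraries compared called 3128. The authors' deposited adjusted p called 2375, of which 1374 were shared, all in the same direction, from the same counts. Genes raised at both times numbered 144, with 34.0 expected by chance (Fisher's exact test, two-sided, p = 3.41e-52), and genes lowered at both 10, with 6.1 expected (p = 0.139). The 144 depends on the 1 h calls and was 57 (9.2 expected) with only the libraries compared, 88 with the replicate block and 226 (97.4 expected) without treated library 2 of 1 h. EGR1, FOS, SPRY4, DUSP6, SPRY2, MAFF, PTGS2, CTGF, KL and FGFR1 were among the shared raised genes. Across all genes, which are not independent replicates, the 1 h and 24 h effects in Kl had a Pearson r of 0.14 and a Spearman rho of 0.03.

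**Figure D3:**
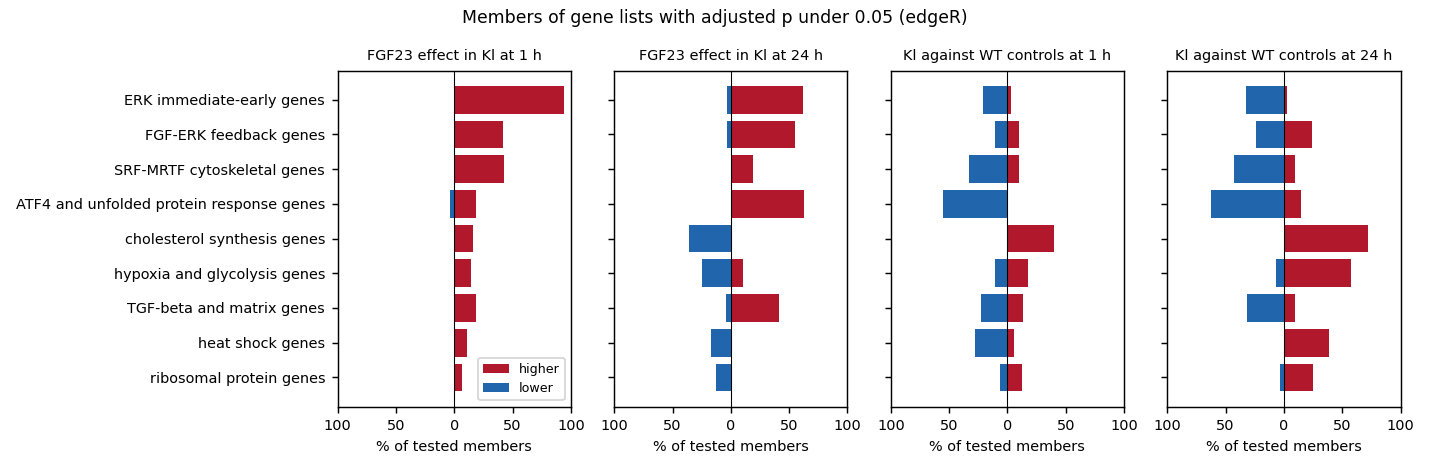
Percent of the tested members of 9 gene lists called higher (to the right) or lower (to the left) for the FGF23 effect in Kl at 1 h and 24 h and for Kl against WT controls at 1 h and 24 h. Immediate-early genes are higher in 32 of 34 cases with FGF23 at 1 h, and ATF4 genes higher in 17 of 27 with FGF23 at 24 h and lower in 17 of 27 in the untreated Kl line.

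The FGF23 effects in Kl and in WT were compared by a test of their difference, which sets one line against the other rather than Klotho alone, as the lines also differed in 4183 genes without FGF23 at 24 h. At 1 h the early ERK genes EGR3 (7.59), EGR1 (7.16 ± 0.271 SE, adjusted p = 1.66e-13), EGR2 (6.42), FOS (5.69 ± 0.435), FOSB (5.37), ARC (5.06), MAFF (3.66), PTGS2 (3.40) and JUNB (2.93), an AP-1 subunit gene, responded more in Kl. EGR4 stood at 10.16 from counts near 0 in the other groups. The messenger decay gene ZFP36 (2.65) and the growth brake BTG2 (1.14) passed, as did the inhibitors SPRY4 (2.50), DUSP6 (2.32, adjusted p = 3.6e-08), SPRY2 (1.22), DUSP1 (1.21) and DUSP5 (2.02), a nuclear phosphatase of ERK. CTGF (2.40), CYR61 (1.40), ID1 (0.85) and CEBPB (0.77) followed. TXNIP (-1.03) and the potassium channel gene KCNJ2 (-0.88) responded in the other direction, as did the uncertain TBC1D3G (-3.53). The receptor gene FGFR1 (0.31, adjusted p = 0.259) and the ETS genes ETV4 (1.29, adjusted p = 0.292) and ETV5 (1.18, adjusted p = 0.598) did not pass, in a test that found 2% of the smallest simulated changes, which are closest to that of FGFR1, and 56% of those of 2 times.

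Immediate-early genes differed in 26 of 34 cases (32 adjusted over the list alone), feedback genes in 9 (11 adjusted over the list alone), SRF-MRTF genes in 4 (8 adjusted over the list alone) and ATF4 genes in 1 (3 adjusted over the list alone), and these lists held with an estimated correlation (adjusted p = 7.57e-13, 6.59e-05, 0.000469 and 0.0296). The receptor complex (0 members, 3 adjusted over the list alone), NF-kB (1), TGF-beta (2), cholesterol (1), hypoxia (1) and mitochondrially encoded genes (0) passed only with the preset correlation, with 0.112, 0.171, 0.329, 0.388, 0.492 and 0.388 for the estimated one. In edgeR 131 genes differed, 126 with a higher effect in Kl and 5 with a lower one, against 1508 at an unadjusted p under 0.05. With only the 12 libraries of 1 h the count was 60, and FOSB, ARC, CEBPB, TXNIP and KCNJ2 lost their call.

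At 24 h the FGF markers again responded more in Kl. ETV4 differed by 4.64 ± 0.441 (SE, adjusted p = 9.06e-08), EGR1 by 4.05, SPRY4 by 3.73 (adjusted p = 1.75e-11), ETV5 by 3.35, DUSP6 by 3.12 and SPRY2 by 1.26. CHAC1 (3.34), PSAT1 (1.59, adjusted p = 1.29e-12), TRIB3 (1.45), SLC7A5 (1.71) and SLC7A11 (2.33) of the ATF4 list differed as well. PAPPA2 (3.22), ELSPBP1 (2.75), the pseudogene ASNSP1 (2.75) and FUT1 (2.68, adjusted p = 9.55e-12), which makes the H blood group antigen, were next. FGFR1 differed by 0.59 ± 0.104 (adjusted p = 0.000634), and FOS, at 1.14, did not pass (adjusted p = 0.128). TGFB1 (1.07), FN1 (0.58), KLF10 (0.90), IER3 (1.82), KLF4 (0.75), the pluripotency factor gene, CTGF (1.84), PTGS2 (2.21) and the proliferation marker MKI67 (0.37) rose more in Kl. ACAT2 (-0.49), LSS (-0.47), MVD (-0.62) and EBP (-0.46) of sterol synthesis, ID2 (-0.53) and RPS2 (-0.49) differed the other way. Larger negative differences in TXLNB (-1.58), PRR35 (-1.48), the hormone gene GNRH2 (-1.45), the kinase gene SIK1 (-1.42) and the uncertain SMN1 (-2.10) had adjusted p from 0.0264 to 0.046 and were lost under some alternatives. SIK1 has a near-identical copy in SIK1B and is uncertain too.

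ATF4 genes differed in 15 higher cases and in MANF, which was lower (17 and 1 adjusted over the list alone), feedback genes in 15 higher and 1 lower (16 and 1 adjusted over the list alone) and immediate-early genes in 12 higher and 1 lower (21 and 1 adjusted over the list alone). These held with an estimated correlation (adjusted p = 2.93e-09, 4.46e-05 and 4.46e-05). Cholesterol (8 lower), TGF-beta (5 higher, 1 lower), SRF-MRTF (3), NF-kB (2) and calcineurin-NFAT genes (NFATC1 higher) passed with the preset correlation and each had 0.181 with the estimated one. Ribosomal protein (3 lower) and heat shock genes (0) had 0.196, and G2 and mitosis genes (3 higher) 0.336. The count was 673 genes, 438 higher and 235 lower, against 2836 at an unadjusted p under 0.05 and 2515 with only the 12 libraries of 24 h.

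Set against the 1 h effect, the 24 h effect in Kl was smaller for early factor genes and larger for ETV4 and ATF4 list genes, with dose and time both different. EGR3 (-5.35), FOSB (-5.31), EGR2 (-4.61), ARC (-3.86), FOS (-3.81 ± 0.434 SE, adjusted p = 1.6e-06), EGR1 (-3.33 ± 0.279), JUNB (-2.48) and the stress gene GADD45B (-2.46) had lower effects at 24 h, as did ZFP36 (-1.82), JUN (-0.90), CYR61 (-1.12) and SIK1B (-2.17), a near-identical copy of SIK1 and thus uncertain. BTG2 (-1.63) differed by more than its rise at 1 h, so its 24 h effect was negative. ETV4 (3.78 ± 0.358, adjusted p = 9.77e-08), CHAC1 (2.998), FUT1 (2.59), ADM2 (2.49), a peptide hormone of the calcitonin family, SLC7A11 (2.22), JDP2 (2.07), a repressor of AP-1, PSAT1 (1.56), TRIB3 (1.13) and SLC7A5 (1.23) had larger effects. SPRY4 (1.03, adjusted p = 0.00809), DUSP6 (0.76, adjusted p = 0.0233) and ETV5 (2.06, adjusted p = 0.0193) were also larger, and FGFR3 (-0.50, adjusted p = 0.0107) smaller, while FGFR1 (0.22, adjusted p = 0.21) and KL (0.20, adjusted p = 0.382) did not pass. MVD (-0.83), LSS (-0.62), NSDHL (-0.58) and DHCR7 (-0.45) of sterol synthesis, HSPA8 (-0.73) and the glucose transporter gene SLC2A1 (-0.60) had lower effects at 24 h than at 1 h.

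Immediate-early genes had lower effects at 24 h in 23 of 34 cases (27 lower and 1 higher adjusted over the list alone) and ATF4 genes higher ones in 13 of 27 (15 higher and 2 lower adjusted over the list alone), and both held with an estimated correlation (adjusted p = 1.06e-07 and 2.89e-07). Cholesterol genes were lower in 9 (14 adjusted over the list alone, camera adjusted p = 2.34e-10, and 0.0545 with an estimated correlation), and feedback genes went both ways, 6 up and 3 down (9 and 6 adjusted over the list alone, adjusted p = 0.0926). SRF-MRTF, heat shock, hypoxia, G2 and ribosomal protein genes passed with the preset correlation and had 0.104, 0.222, 0.35, 0.35 and 0.417 with the estimated one. In edgeR 1039 genes differed, 462 higher and 577 lower, against 3902 at an unadjusted p under 0.05, and 246 differed with only the 12 Kl libraries, where ARC, GADD45B, DUSP6, ETV5, FGFR3, DHCR7 and SLC2A1 lost their call. With library size alone as scaling, the direction split turned from 44.5% to 56.3% higher. In WT the 24 h and 1 h effects differed for 0 genes in edgeR and in DESeq2, with 350 at an unadjusted p under 0.05 (EGR1 -0.22 ± 0.268 SE, ETV4 0.43 ± 0.518).

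Untreated Kl and WT cells were compared at each time. In the 1 h controls COL3A1, a fibrillar collagen, lay higher in Kl by 2.90, CHL1 and NTM, neural adhesion proteins, by 2.17 and 1.97, PREX2, an activator of RAC, by 1.78 and MYC by 1.10. CTNND2 (ENSG00000169862, chromosome 5, 10971840 to 11904043), a neuronal catenin, lay lower by 2.49 ± 0.127 (SE, adjusted p = 1.04e-14). The polarity gene CRB3 (-2.81), ELSPBP1 (-2.57), the myosin light chain gene MYL9 (-2.55), the keratin gene KRT17 (-2.51), the epithelial protease gene ST14 (-2.50), the adenylate cyclase gene ADCY2 (-2.50), the kinase gene NRK (-2.46), the pseudogene transcript DUXAP8 (-2.38) and ZNF439 (-2.35) followed. ID1 (-1.36), FN1 (-0.59) and KLF4 (-0.79) lay lower. The ATF4 list genes TRIB3 (-0.74), PSAT1 (-0.64), SLC3A2 (-0.69) and CEBPB (-0.94) lay lower, and the sterol genes ACAT2 (0.56), FDPS (0.46), DHCR7 (0.35) and SQLE (0.26) higher. FGFR1 was lower by 0.21 ± 0.074 (adjusted p = 0.0466) and ETV4 higher by 0.91 (adjusted p = 0.0382), both lost under some alternatives, while EGR1 (-0.53, adjusted p = 0.108), DUSP6 (0.35, adjusted p = 0.178) and SPRY4 (0.59, adjusted p = 0.0611) did not pass.

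In the 24 h controls FAM84A, a gene linked to cell morphology, lay lower in Kl by 2.56 ± 0.083 (SE, adjusted p = 7.05e-20), FUT1 by 2.57, CTNND2 by 2.57, NRK by 3.22, ADCY2 by 2.69, ST14 by 2.66, the peroxisomal gene PXMP4 by 2.77, ZNF439 by 2.68, ZNF788P by 2.66 and PURPL, a suppressor of p53, by 2.58. PREX2 (1.89), SCUBE1 (1.64), QPRT (1.53) of NAD synthesis, MAP1A (1.49) of microtubules and MYC (1.06) lay higher, and SERF1A (1.64) did with the uncertainty of its copies. The neurofilament gene NEFM (-2.10), GAP43 (-1.14) of axon growth and MAP2 (-0.50) lay lower. PSAT1 (-1.14), TRIB3 (-1.13), SLC7A11 (-1.71) and SLC3A2 (-0.93) were lower, and ACAT2 (0.82), DHCR7 (0.57), SQLE (0.56) and FDFT1 (0.46) higher. Hypoxia and glycolysis list genes HK2 (1.32), BNIP3 (0.85), LDHA (0.65) and PGAM1 (0.53) were higher. Receptor genes FGFR4 (0.45, adjusted p = 0.000654) and FGFR2 (0.28, adjusted p = 0.00404) were higher, FGFR1 (0.02, adjusted p = 0.873) did not pass, EGR1 was lower by 1.01 and DUSP6, SPRY4 and ETV4 were higher by 0.76, 0.68 and 0.99.

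MYL9, ID1, TRIB3, CEBPB, PXMP4, the spindle genes TPX2 (-0.52 at 24 h) and AURKA (-0.47) and the signaling enzyme gene PLCG1 (-0.28) lie on chromosome 20, and PSAT1 and KLF4 on chromosome 9. Among genes with a mean of 2 CPM or more, chromosome 20 had a median of -0.37 at 1 h and -0.33 at 24 h, and chromosome 9 had -0.32 and -0.30. Chromosome 7 had 0.23 and 0.24. By list, the ATF4 genes were lower in 15 of 27 cases at 1 h (17 lower and 1 higher adjusted over the list alone, adjusted p = 5.76e-11) and in 17 at 24 h with 4 higher (17 and 5 adjusted over the list alone, adjusted p = 6.17e-13), and both held with an estimated correlation. The receptor complex held at both times (6.24e-06 and 4.12e-06 with an estimated correlation), but did not pass without KL (adjusted p = 0.787 and 0.393). Cholesterol genes were higher in 10 of 25 at 1 h (10 adjusted over the list alone, adjusted p = 8.51e-06, and 0.27 estimated) and in 18 at 24 h (20 adjusted over the list alone, adjusted p = 4.65e-16, and 0.00896 estimated). At 24 h immediate-early genes, 11 lower and 1 higher (12 and 1 adjusted over the list alone), and neuronal and adrenal markers, 6 lower and 2 higher (7 and 2 adjusted over the list alone), also held (0.0357 and 0.0182 estimated), while hypoxia and glycolysis genes, 16 higher and 2 lower, did not (adjusted p = 2.72e-08, and 0.0743 estimated). With the preset correlation alone, immediate-early, SRF-MRTF, TGF-beta and distal nephron genes passed at 1 h (0.27, 0.396, 0.448 and 0.27 estimated). So did SRF-MRTF, heat shock, TGF-beta, G2, mitochondrially encoded and ribosomal protein genes at 24 h (0.361, 0.361, 0.38, 0.38, 0.443 and 0.454 estimated). In edgeR 2842 genes differed at 1 h, 1321 higher and 1521 lower in Kl, and 4183 at 24 h, 2040 higher and 2143 lower, against 4952 and 6106 at an unadjusted p under 0.05. At 24 h the share higher was 48.8%, and 32.6% with library size alone.

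**Figure D4:**
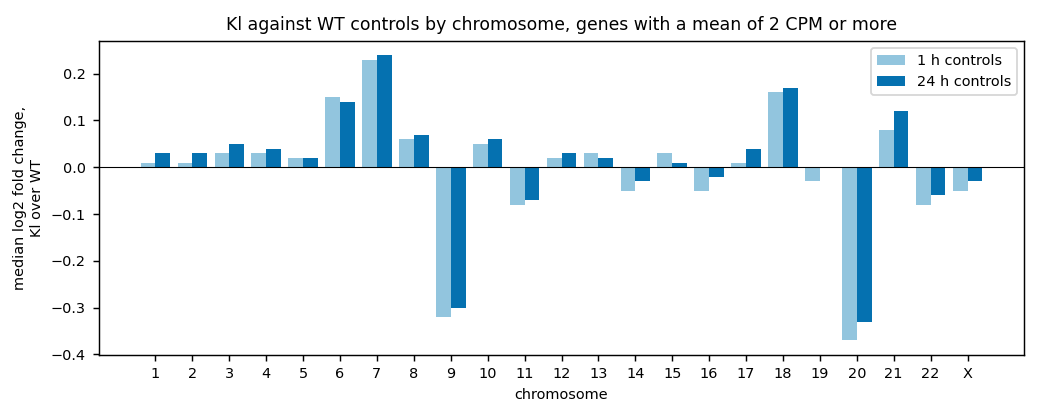
Median log2 fold change of Kl over WT controls for the genes of each of 23 chromosomes with a mean of 2 CPM or more, at 1 h and at 24 h. Chromosomes 20 and 9 lie lowest, at -0.37 and -0.32 at 1 h, and chromosome 7 highest at 0.23.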

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

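The tests of gene length, of a weaker or later response in library 3, of copy number, of the cholesterol genes against the 1 h controls, of the directions of genes called in both comparisons, of the splits in WT at 24 h with only its own libraries, and of the groupings that mix libraries in both effects of a comparison were chosen after the results were seen. The other tests were set down first. All patterns weighed here were noticed in the data, and what they might mean is a hypothesis.

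Between groups, 131 genes differed in their FGF23 effect between Kl and WT at 1 h, 673 at 24 h, and 1039 between 24 h and 1 h in Kl. When libraries were regrouped at random, 1 of 100 groupings, the real one, reached the 673 of 24 h (highest other 538). This argues against chance for an FGF23 effect at 24 h, but not for a difference between the lines by itself. Every other grouping that called any gene at 24 h kept the real FGF23 grouping of the Kl libraries. The 131 of 1 h were reached by 18 of 100 (highest other 489) and the 1039 by 5 of 100 (highest other 2208), so chance is not excluded for these counts by that share. The share is a weak test of chance, since 13 of the 17 other groupings that reached 131 kept the real FGF23 grouping of the Kl libraries, and all 4 that reached 1039 kept that of 24 h, and so still held an FGF23 effect. Of the 73 groupings that mixed treated with control libraries in both effects of a comparison, 4 reached 131 (highest 489), 0 reached 673 (highest 0) and 0 reached 1039 (highest 687). These 4 (489, 429, 257 and 210) all put Kl control library 3 with treated Kl libraries 1 and 3, or the mirror of it, but the other groupings that did so called 0 to 8, so the counts hang on the WT grouping too. The highest, several times the real count, point to a structure of the 1 h libraries that was not resolved. For single effects, which have 10 possible groupings and so no share under 0.05, 2 of 10 reached the 859 of Kl at 1 h (highest other 1214), 1 of 10 the 1524 of Kl at 24 h (highest other 0), 1 of 10 each the 2842 and 4183 between the lines (highest other 0), and 10 of 10 the 0 of WT at either time. In WT the 24 h minus 1 h count of 0 was reached by 100 of 100. Any grouping reaches a count of 0, so the shares for these WT counts of 0 test nothing. The 111 genes of WT at 24 h in its own libraries were reached by 1 of 10 (highest other 3).

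The Kl libraries treated for 1 h lay further apart than any other group, with a median SD of 0.205. A technical trend with GC content in library 1 could explain part of it, with a rho across genes of 0.79 against sizes of at most 0.55 in other groups (0.73 in size for library 2). Removing the GC trend from every library, so not from library 1 alone, lowered the SD to 0.136, still above the 0.067 to 0.098 of other groups. A weaker response in library 3 was argued against by the 16 feedback genes that rose in Kl at 24 h, 13 of them higher there than in library 2 (median 0.39, quartiles 0.06 and 0.73). Over all 29 feedback genes 21 were higher (median 0.2). Higher feedback genes do not tell a stronger response from a later one. The 873 genes raised at 24 h left a weaker response open (median 0.02). A later point of the response in library 3 is open. Against library 2 in log2 CPM, EGR1 stood at -0.5 and FOS at -0.96. Of the other genes picked for this, EGR2 (-0.64), EGR3 (-1.47), FOSB (-1.76) and NR4A2 (-1.09) lay lower too. ETV4 (1.5), ETV5 (1.73), SPRED1 (1.17), FOSL1 (0.89), TNFRSF12A (2.23), F3 (1.57) and SPRY4 (0.58) lay higher, and DUSP6 (0.02) hardly differed. The early genes ARC and NAB2 stood at 1.98 and 2.21, and the immediate-early list had a median of -0.07 with 16 of 34 higher. The genes were picked after the values were seen and do not decide it. Gene length is open too (rho -0.16, up to 0.26 in size elsewhere), and no other biological explanation was tested.

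FGF23 at 24 h ran against part of what set the Kl line apart: of genes lower in the Kl controls of 1 h, 169 rose with FGF23 at 24 h (74.6 expected), and of those higher there 134 fell (48.3 expected), while 66 of the lower fell (55.7 expected) and 76 of the higher rose (64.8 expected). The use of the same controls on both sides, which may produce such a reversal, is argued against as the whole cause by the 1 h controls, which share no library: 68.1% of the 445 genes called in both went opposite ways (67.1 to 69.7% without any one chromosome, 50.5% expected), while the r across all genes, -0.11 (-0.117 to -0.1 without any one chromosome, rho -0.07, covariance -0.00623), is too small to decide. With the shared controls r was -0.32 where 20 simulated tables without any difference between the groups gave a mean of -0.52, and the covariance was -0.0216 where they gave -0.00539. Controls of 24 h that were out of place are argued against for the ATF4 list, whose median stood at 0.99 (SD 1.02) in treated Kl cells over the Kl controls of 1 h (18 higher, 1 lower), where controls drifted by 0.19 in Kl and 0.46 in WT. The immediate-early and feedback lists stood at 0.84 (22 higher, 2 lower) and 0.64 (17 higher, 1 lower), with drifts of 0.18 and 0.09 in Kl and 0.25 and 0.03 in WT. The Kl drifts come from the 24 h controls in question, so only the WT drifts are independent of them. For the lists that fell, controls out of place stay open, since cholesterol genes stood at -0.01 over the 1 h controls (6 higher, 4 lower) and heat shock genes at -0.01, as the Kl controls themselves rose by 0.16 and 0.2 from 1 h to 24 h (-0.03 and -0.13 in WT), and a biological reading was not tested.

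Whole chromosomes lay lower or higher in Kl than in WT, which bears on TRIB3, ID1 and PSAT1. A difference in copy number between the lines is left open. On chromosomes 7, 9 and 20, 100 percent of the 35 windows of 10 Mb had the sign of their chromosome at both times, against 69.7% elsewhere. These chromosomes were picked for their medians, and the test asked that no other chromosome have all windows of its own sign. Chromosomes 6, 18 and 21 did, but their medians were shifted too, at 0.15, 0.16 and 0.08 at 1 h and 0.14, 0.17 and 0.12 at 24 h. The libraries of the lines lay apart on chromosomes 6 and 21 but overlapped on 18. The condition of the test was thus not met, and the windows leave copy number undecided. Over 23 chromosomes the medians of 1 h and 24 h had an r of 0.99. A GC trend between the lines is argued against by a chromosome 20 median of -0.33 with the trend removed. Whether the change arose with the transfection or in culture was not tested.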

How the results depend on the processing

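The voom, GC and extra leave-out alternatives were chosen after the results were seen; the pseudocount alternative does not apply because counts were deposited. Over 488 named gene values and 9216 alternatives, 8420 kept their side of the threshold, 610 weakened, 186 strengthened and 0 reversed. Of the 488 values, 313 kept their side under every alternative, and the rest changed it under at least 1. EGR1, SPRY4 and DUSP6 kept their calls in Kl at both times throughout. Scaling moved no median by more than 0.07. Counts that moved follow, and the cause was not tested except that fewer libraries leave out the spread of the others. FGF23 in Kl at 1 h (859) gave 1332 with no filter, 90 with only its libraries, 176 with the replicate block, 229 with voom and 135 with the GC trend removed in only its libraries; leaving out one library gave 403 (without control 2) to 2636 (without treated library 2). Kl at 24 h (1524) gave 3128 with only its libraries, 2893 with the block, 3177 with voom, 2368 with GC removed and 3548 with both; 829 (without control 3) to 2837 (without treated library 1 of 1 h). WT at 1 h (0) gave 12 with no filter and 5 with the block (0 to 0 on leaving one out), and WT at 24 h (0) 7, 111 with only its libraries, 97 with the block, 2 with voom and 159 with GC removed in its libraries (0 to 1). Kl minus WT at 1 h (131) gave 369 with no filter, 211 in DESeq2, 60 with only its libraries, 200 with GC removed and 78 with both (89 to 530, the latter without Kl treated library 2), and at 24 h (673) 2515, 2360 with the block, 2290 with voom, 1358 with GC removed and 2897 with both (381 without Kl control 3, to 1634 without treated library 1 of 1 h). For 24 h minus 1 h, Kl (1039) gave 246 with only its libraries, 363 with the block, 637 with voom and 499 with GC removed in its libraries (529 without treated library 2 of 24 h, to 2672 without treated library 2 of 1 h), and WT (0) gave 5 with no filter and 1 with the block (0 to 0). Kl against WT at 1 h moved under none (2044 to 4172 on leaving one out); at 24 h (4183) it gave 6757 with only its libraries, 6869 with the block, 6573 with voom and 7046 with GC removed in its libraries (3124 to 5517). Genes raised at both times in Kl (144) gave 219 with no filter, 57 with only their libraries, 88 with the block, 219 with GC removed and 85 with both (100 without Kl control 2 of 1 h, to 226 without treated library 2), and genes lowered at both (10) gave 33 with library size, 24 in DESeq2, 0 with only their libraries, 2 with the block, 1 with voom, 35 with GC removed and 0 with both (1 to 46). Of 75 list calls 26 held with an estimated correlation, all in the same direction, and fry called 90. List medians close to 0 changed sign with library size for NRF2, S phase and histone genes in Kl at 1 h, WNT genes at 24 h, the receptor complex for 24 h minus 1 h, ribosomal protein genes for Kl minus WT at 1 h, and feedback, S phase and phosphate genes between the 24 h controls. With 15.8 to 30.4 M counts per library, depth limits genes near 0 counts, such as EGR4 and KL in WT.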

Other observations

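Which of these tests were chosen after the result was seen: the fold changes between controls of different times, the chromosome 5 array and the gene lengths. Genes for which Kl cells with FGF23 reached the WT level included FUT1, the fucosyltransferase of the H antigen, at 14.1 CPM in treated Kl cells, 2.36 in their 24 h controls and 14.0 in WT controls. In Kl at 24 h genes for phosphate handling moved apart from any list call: the phosphate importers SLC20A1 (0.34) and SLC20A2 (0.44), the kinase gene SGK1 (0.67), which FGF23 uses to act on renal phosphate transport, and GALNT3 (0.31), which protects FGF23 from cleavage, rose (list adjusted p = 0.285, 4 called, and 4 higher and 1 lower adjusted over the list alone). At 1 h SLC20A1 (0.33), FAM20C (0.40), the kinase that phosphorylates FGF23, and WNK4 (0.68), a kinase of salt transport, rose (list adjusted p = 0.071, 3 called, 6 adjusted over the list alone). Other genes that rose at 24 h, picked after the values were seen, were ATF4 itself (1.31), ASNS (1.57), DDIT3 (0.55), ADM2 (2.36), the calcium and phosphate hormone STC2 (1.54) and VEGFA (0.85), with ETV1 (1.62) of the ETS family.

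Hypoxia and glycolysis genes split in Kl at 24 h: VEGFA, SLC2A3 and NDRG1 rose while BNIP3, LDHA, PDK1, PGAM1, EGLN3, PFKFB4 and PFKFB3 fell (4 higher and 9 lower adjusted over the list alone, list adjusted p = 0.238). Over the Kl controls of 1 h the list stood at a median of 0.01 in these treated cells (7 rose, 4 fell). The Kl controls themselves rose by 0.2 from 1 h to 24 h (-0.05 in WT), so controls out of place stay open for the decreases. Between controls of 24 h and 1 h, ATF4 genes had a median of 0.46 in WT (14 rose, 5 fell) and 0.19 in Kl (9 rose, 1 fell), and cholesterol genes -0.03 in WT (1 rose, 1 fell) and 0.16 in Kl (10 rose, 0 fell).

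The lists and times given here did not pass for FGF23 in Kl. WNT target genes had 3 higher at 24 h (adjusted p = 0.238), FOXO and insulin-IGF genes 4 higher and 1 lower at 1 h (adjusted p = 0.691) and 3 higher and 1 lower at 24 h (0.86), and calcineurin-NFAT genes 1 higher at 1 h, NFATC1 (0.775), and 0 at 24 h (0.238). S phase genes had adjusted p = 0.2 and 0.589, replication-dependent histone genes 0.983 and 0.965, interferon response genes 0.983 and 0.482, and mitochondrially encoded genes 0.146 and 0.853 at 1 h and 24 h. Among cell type markers, neuronal and adrenal genes had NEFM and GAP43 higher at 24 h (0.285), while proximal tubule markers (0.596 and 0.482), distal nephron and collecting duct markers (0.445 and 0.923) and fibroblast and endothelial markers (0.983 and 0.285) had 0 called by edgeR. Blood cell markers had too few tested members for a list test, with LCP1 called at 24 h. G2 and mitosis, NRF2 and ribosomal protein genes did not pass at 1 h (0.151, 0.236 and 0.138). In the 1 h controls distal nephron markers GATA3 (-0.38), CALB1 (-1.43) and PVALB (-1.74) lay lower in Kl (0.27 for the list with an estimated correlation).

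An array of near-identical genes on chromosome 5 between BASP1 and the centromere lay higher in Kl controls, with TAF11L11 at 3.67 and 2.16, TAF11L12 at 3.38 and 2.60, TAF11L14 at 4.01 and 2.99 and H3.Y at 3.31 and 2.34 at 1 h and 24 h, and single copies are uncertain. The 94 genes lower in WT at 24 h in the fit to its own 6 libraries had a median log2 fold change of -0.17 and a median gene length of 14.72 kb, against 4.55 kb for tested genes, and across 11872 genes the rho of effect and length was -0.35. The share of genes lower there did not come with a response of EGR1, SPRY4 or ETV5.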
